A study of Elaeis guineensis with 38 samples.

How the data were processed

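Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on leaf (frond 0) of oil palm, Elaeis guineensis, per the labels. The labels describe 38 samples from 10 clonal palms raised from 1 ortet, the palm from which the clones were propagated. They comprise 19 immunoprecipitated libraries and 19 input libraries of chromatin that was not immunoprecipitated. Of the palms, 5 bore normal and 5 bore mantled fruit. The antibodies were mouse monoclonals against H3K4me3 and H3K27me3. The labels describe no H3K4me3 library of mantled palm 673, which left 4 mantled and 5 normal palms for H3K4me3 and 5 of each for H3K27me3. Each palm is a separate plant, so palms were the replicates.

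The submitters' processing notes name FastQC 0.11.3, Bowtie2 2.2.5, SAMtools 1.9 and MACS2 2.1.1.20160309. Per the file headers, the authors called peaks with MACS2 separately for each immunoprecipitated library against its own input, on paired-end fragments, with at most 1 fragment kept per position, a q cutoff of 0.05 and a genome size of 221 Mb. H3K4me3 lists were called as narrow peaks and H3K27me3 lists in the caller's broad mode, per the file headers, so widths and enrichments of the marks come from different procedures. The deposited pileup is a signal of stacked fragments and the deposited fold enrichment is a ratio to the local background. The caller takes both at the summit of a narrow peak and averages them over a broad one. The p and q columns are deposited as −log10 values. The header also gives the fragments that entered each call, which is the depth used here. The input was the larger library in each of the 19 calls and was scaled down to the ChIP library.

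Positions are given as in the files, counted from 1 on numbered scaffold pieces. The genome build was not given in the sources used here beyond the names of these pieces. The gene table at hand belongs to another assembly, EG11, whose sequences carry other names, and its coordinates were not used. All comparisons that needed genes were therefore not run. These were the share of peaks at transcription starts, the genes with both marks, and the tests of 19 gene lists. The homologues of DEFICIENS, a class B MADS-box gene known to be involved in mantling, had also been planned and were not examined. For the same reason exon, intron and promoter positions are not stated.

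Peaks of the libraries of a mark that shared at least 1 bp were merged into regions, and each region was scored as with or without a peak in each library. For each mark, log2 peak number and log2 median fold enrichment were compared between phenotypes with two-sided exact permutation tests over all splits of the libraries. These 4 tests were adjusted together by the Benjamini-Hochberg method. The fold enrichment of a peak is the authors' own value within its list, so medians were compared only together with depth. Regions were tested with Fisher's exact test and Benjamini-Hochberg adjustment, and regions with a peak in every library of one phenotype and none of the other were counted in all 126 splits of the libraries. Similarity of lists was the base-pair Jaccard index, the shared length divided by the combined length, averaged within and between phenotypes, with an exact permutation of the labels. Marks were compared by exact permutation over all 92378 splits. The comparison was repeated within palms by an exact sign-flip test over the 9 palms with both marks. The pairing comes from the labels, which give both libraries the same palm. The deviations of libraries of the same palm from their group means correlated at r = 0.12 for log2 peak number and at r = 0.049 for log2 median width.

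The regions named in the text follow a rule fixed before the data were examined. For each mark it takes the 10 regions with a peak in most libraries, with ties ordered by median fold enrichment. For each mark and direction it takes the 5 regions with the largest difference between phenotypes in the share of libraries, with ties ordered by Fisher p and then median fold enrichment. It takes up to 5 regions with both marks by the first ranking. A region's fold enrichment in a library is that of its strongest peak, and medians and standard deviations are over the libraries with a peak. Local background was computed from each peak's pileup and fold enrichment, with the caller's pseudocount of 1, and expressed as a multiple of the average that the header's genome size implies. The genome of oil palm is larger than this setting, so an average over the whole genome would be lower and the multiples higher. They compare peaks with one another and are not copy numbers.

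After the lists had been examined, overlap between lists of both marks was added, as the percentage of the shorter list's regions with a peak in the other list. For it the peaks of all 19 libraries were merged. Mark-specific region sets were taken from the normal palms. A region entered the H3K4me3 set with a peak in at least 60% of normal H3K4me3 libraries and at most 25% of normal H3K27me3 libraries, the H3K27me3 set by the converse, and the common set with at least 60% of both. Each normal library was left out of the sets on which it was scored. Leaving a library out loosened the limit of 25% for its mark. Every region that this added to the set of the other mark had a peak in that library. Regions that needed the library to reach 60% left the set of its own mark. The order of the 2 shares in a normal library is therefore biased against its label. The counts of regions with both marks were repeated with the marks of palm 754 exchanged, without palm 754, and without the 5 H3K27me3 libraries in reversed order. Shares carry 95% Wilson intervals, which cover counting error over regions only. Alternatives were a −log10 q of at least 5, a fold enrichment of at least 3, equal numbers of the strongest peaks, merging across 500 bp, overlap by 50% of the shorter peak, linear means, peak number divided by the fragments of the library, a difference of at least 0.6 in the share of libraries, and leaving out each library. The code was tested on simulated data with 200 regions made to separate the phenotypes in either mark; the count of separated regions returned all 200, as their construction fixes, which says nothing of power. The adjusted Fisher test recovered 0 of them in either mark, because its smallest p at these group sizes is 0.00794. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.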

Results

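Mantling is an abnormality of oil palm flowers and fruit that arises in some palms propagated by tissue culture, in which stamens take on the form of carpels. H3K4me3 is a histone mark typical of the starts of active genes, and H3K27me3 is a mark of Polycomb silencing. The series mapped both marks in leaf of clonal palms with normal or mantled fruit. The 19 peak lists held 24560 peaks on 3798 scaffold pieces. H3K4me3 lists held 1738 ± 1259 peaks in normal palms (SD, n = 5) and 1489 ± 1655 in mantled palms (SD, n = 4). H3K27me3 lists held 967 ± 341 peaks in normal palms (SD, n = 5) and 1016 ± 447 in mantled palms (SD, n = 5). Depth was uneven. The fragments kept ranged from 229258 to 7883375 in the H3K4me3 libraries and from 253624 to 10374962 in the H3K27me3 libraries, and inputs held 7091506 to 13325762. Across libraries of a mark, 45.7% of the 5826 H3K4me3 regions and 42.3% of the 3470 H3K27me3 regions had a peak in 1 library only.

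H3K4me3 was found at 55 regions in all 9 libraries. The region with the highest median enrichment lay on p5.00_sc00176_p0025 from 1362 to 1714, with a fold enrichment of 5.21 ± 2.22 (median, SD, n = 9). Next were p5.00_sc00001_p0869 from 6536 to 7062, at 3.88 ± 2.13, and p5.00_sc00252_p0006 from 952 to 2030, at 3.52 ± 1.15 (medians, SD, n = 9). The other 7 of the 10 highest-ranked regions had medians from 2.76 to 3.47. Each of the 10 also had H3K27me3 peaks in 8 to 10 of the 10 H3K27me3 libraries, and their local background was 19.1 to 449 times the average at the caller's genome size.

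The first comparison asked where H3K4me3 differed between normal and mantled palms. No region had a peak in every library of one phenotype and in none of the other. The strongest leanings towards mantled palms were on p5.00_sc01104_p0001 from 300 to 585, marked in 4 of 4 mantled and 1 of 5 normal libraries with a fold enrichment of 3.14 ± 1.59 (median, SD, n = 5), and on p5.00_sc02691_p0001 from 7706 to 8072, marked in 3 of 4 and 0 of 5 with 2.89 ± 1.58 (median, SD, n = 3). Next were p5.00_sc00061_p0067 from 21679 to 22510 in 4 mantled and 2 normal libraries, and p5.00_sc00159_p0001 from 19244 to 20792 and p5.00_sc00780_p0001 from 12599 to 12903, each in 3 mantled and 1 normal library. At a fold enrichment of at least 3, p5.00_sc00061_p0067 was left with a peak in 0 libraries, p5.00_sc01104_p0001 in 3, p5.00_sc00780_p0001 in 2 and p5.00_sc02691_p0001 in 1. Towards normal palms, p5.00_sc02166_p0001 from 3127 to 3611, at 3.97 ± 1.5, and p5.00_sc00022_p0103 from 292 to 905, at 3.72 ± 1.07, were marked in 0 of 4 mantled and 4 of 5 normal libraries (medians, SD, n = 4), and in 2 and 1 libraries at a −log10 q of at least 5. A further 3 regions were marked in 1 mantled and 5 normal libraries. They were p5.00_sc01787_p0001 from 9927 to 11476 at 4.82 ± 2.14, p5.00_sc00411_p0001 from 2897 to 3283 at 4.63 ± 1.59, and p5.00_sc00136_p0028 from 19924 to 20365 at 4.53 ± 2.59 (medians, SD, n = 6). Local background was 13.2 to 356 times the average at the 5 regions leaning towards mantled and 1.17 to 11.4 times at the 5 leaning towards normal palms. Peaks of H3K27me3 were present in 5 to 8 of the 10 H3K27me3 libraries at the former and in 1 to 5 at the latter.

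By Fisher's exact test, 0 H3K4me3 regions passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.930), and 44 had an unadjusted p under 0.05, of which 42 leaned towards normal and 2 towards mantled palms. The mantled H3K4me3 libraries had 0.428 times the fragments of the normal ones as a ratio of geometric means (exact permutation p = 0.302, n = 4 and 5), and the mantled H3K27me3 libraries 1.75 times (exact permutation p = 0.508, n = 5 and 5). The mantled H3K4me3 libraries also differed among themselves. Palms 687, 754 and 770 had peaks at 1.62, 2.06 and 3.69% of the H3K4me3 set of normal palms, against 96.8% in palm 765. That of palm 754 had peaks at 91.7% of the H3K27me3 set. How far this accounts for the lean towards normal palms was not tested. With a smallest possible p of 0.00794, 925 completely separated regions would be needed for any of the 5826 to pass the adjustment. The count of separated regions rose from 0 to 40 when mantled palm 765 was left out. Of these 40 regions 39 were marked in normal palms only, and 39 of the 40 had a peak in palm 765. Another split of the same 8 libraries gave 586 such regions, and 4 of the 56 splits gave at least 40.

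H3K27me3 was found at 71 regions in all 10 libraries. The highest medians were on neighbouring-numbered pieces of 1 scaffold, p5.00_sc00158_p0028 from 260 to 864, with a fold enrichment of 4.37 ± 1.15, and p5.00_sc00158_p0027 from 13933 to 14521, with 3.98 ± 1.49 (medians, SD, n = 10). At a −log10 q of at least 5 they had a peak in 2 and 5 of the 10 libraries. They had H3K4me3 peaks in 4 and 3 of the 9 H3K4me3 libraries, and their local background was 1.48 and 2.19 times the average at the caller's genome size. The region on p5.00_sc00108_p0037 from 5605 to 7386 followed at 3.73 ± 1.73 (median, SD, n = 10). The other 7 of the 10 highest-ranked regions had medians from 2.54 to 3.58, and 7 to 9 of the 9 H3K4me3 libraries also had a peak there. The local background was 9.99 to 126 times that average at the 8 regions below the first 2.

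The same question was asked of H3K27me3, and 0 regions separated the phenotypes. Towards normal palms, p5.00_sc00001_p0394 from 292 to 729 was marked in 5 of 5 normal and 1 of 5 mantled libraries with a fold enrichment of 6.27 ± 1.18 (median, SD, n = 6). The regions on p5.00_sc00023_p0028 from 12902 to 13542, at 4.64 ± 1.01, and on p5.00_sc01967_p0002 from 16022 to 17796, at 2.23 ± 0.296, were marked in 4 of 5 normal and 0 of 5 mantled libraries (medians, SD, n = 4). At a −log10 q of at least 5 they were left with a peak in 0 and 1 libraries, and at a fold enrichment of at least 3 the second had 0. Those on p5.00_sc00086_p0048 from 6 to 684 and p5.00_sc00013_p0194 from 421 to 756 were marked in 4 normal and 1 mantled library, the second in 3 libraries at a −log10 q of at least 5. Towards mantled palms no region leaned further than 4 of 5 mantled against 1 of 5 normal libraries. The highest-ranked of these was p5.00_sc01965_p0001 from 2476 to 2816, at 5.25 ± 1.24 (median, SD, n = 5), followed by p5.00_sc00438_p0003 from 26577 to 27077 at 2.71 ± 0.619, p5.00_sc01134_p0001 from 3248 to 3906 at 2.46 ± 0.409, p5.00_sc01537_p0002 from 13554 to 14071 at 2.19 ± 0.555 and p5.00_sc00001_p0766 from 4286 to 4917 at 2.0 ± 0.231 (medians, SD, n = 5). At a −log10 q of at least 5 the first 4 of these were left with a peak in 2 libraries each, and at a fold enrichment of at least 3 the last 3 were left with 0 and p5.00_sc00438_p0003 with 2. Local background was 1.06 to 19.1 times the average at the 5 regions leaning towards normal and 1.28 to 44.5 times at the 5 leaning towards mantled palms. By Fisher's exact test, 0 regions passed after Benjamini-Hochberg adjustment, and 3 had an unadjusted p under 0.05, all 3 leaning towards normal palms.

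No phenotype difference in the number or strength of peaks passed its test. Mantled palms had 0.688 times the H3K4me3 peaks of normal palms as a ratio of geometric means (exact permutation p = 0.548, adjusted p = 0.730, two-sided, n = 4 and 5). The ratio was 1.01 without mantled palm 687 and 0.428 without mantled palm 765 (exact permutation p = 0.982 and 0.161, n = 3 and 5). For H3K27me3 the ratio was 1.01 (exact permutation p = 0.976, adjusted p = 0.976, n = 5 and 5), and it ranged from 0.885 without mantled palm 673 to 1.2 without mantled palm 687. The median fold enrichment was 1.33 times as high in mantled palms for H3K4me3 (exact permutation p = 0.175, adjusted p = 0.698, n = 4 and 5) and 0.849 times for H3K27me3 (exact permutation p = 0.476, adjusted p = 0.730, n = 5 and 5). The smallest p these designs allow is 0.00794. With peak numbers divided by the fragments of each library, both ratios of peak number turned, to 1.61 for H3K4me3 and 0.578 for H3K27me3 (exact permutation p = 0.333 for each). Among peaks with a fold enrichment of at least 3, the ratio of H3K4me3 peak number was 1.34 (exact permutation p = 0.730, n = 4 and 5), and the median enrichment of the H3K4me3 lists was 1.25 times as high in mantled palms (exact permutation p = 0.0317, not adjusted, n = 4 and 5). The difference between the marks in the phenotype effect on log2 peak number was -0.36 (exact permutation p = 0.698, 9 palms), and that on log2 median fold enrichment was 0.48 (exact permutation p = 0.206, 9 palms).

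Peak number followed depth in both marks, and median fold enrichment did in H3K27me3. For H3K27me3, log2 peak number rose with log2 fragments (Pearson r = 0.861, permutation p = 0.00024; Spearman rho = 0.903, permutation p = 0.00094, n = 10), and log2 median fold enrichment fell (r = -0.957, permutation p = 0.00012; rho = -0.891, permutation p = 0.00126, n = 10). After Benjamini-Hochberg adjustment over the 4 relations computed, the Pearson p was 0.00048 for both. Without the 2 libraries farthest from the median depth, r was 0.756 and -0.936. For H3K4me3, r was 0.820 for peak number (exact permutation p = 0.00898, adjusted p = 0.012; rho = 0.767, exact permutation p = 0.0214, adjusted p = 0.0285, n = 9) and 0.645 without the 2 farthest libraries. For the median fold enrichment of H3K4me3, r was -0.595 (exact permutation p = 0.0945, adjusted p = 0.0945; rho = -0.500, exact permutation p = 0.178, n = 9) and -0.373 without the 2 farthest libraries. The H3K4me3 relation of peak number to depth had an r of 0.289 among peaks with a fold enrichment of at least 3. With both measures centred on phenotype and permuted within it, r was 0.889 for H3K27me3 peak number (exact permutation p = 0.00542, adjusted p = 0.0108, n = 10), -0.954 for H3K27me3 median fold enrichment (exact permutation p = 0.000694, adjusted p = 0.00278, n = 10), 0.815 for H3K4me3 peak number (exact permutation p = 0.0149, adjusted p = 0.0199, n = 9) and -0.508 for H3K4me3 median fold enrichment (exact permutation p = 0.204, adjusted p = 0.204, n = 9).

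**Figure D1:**
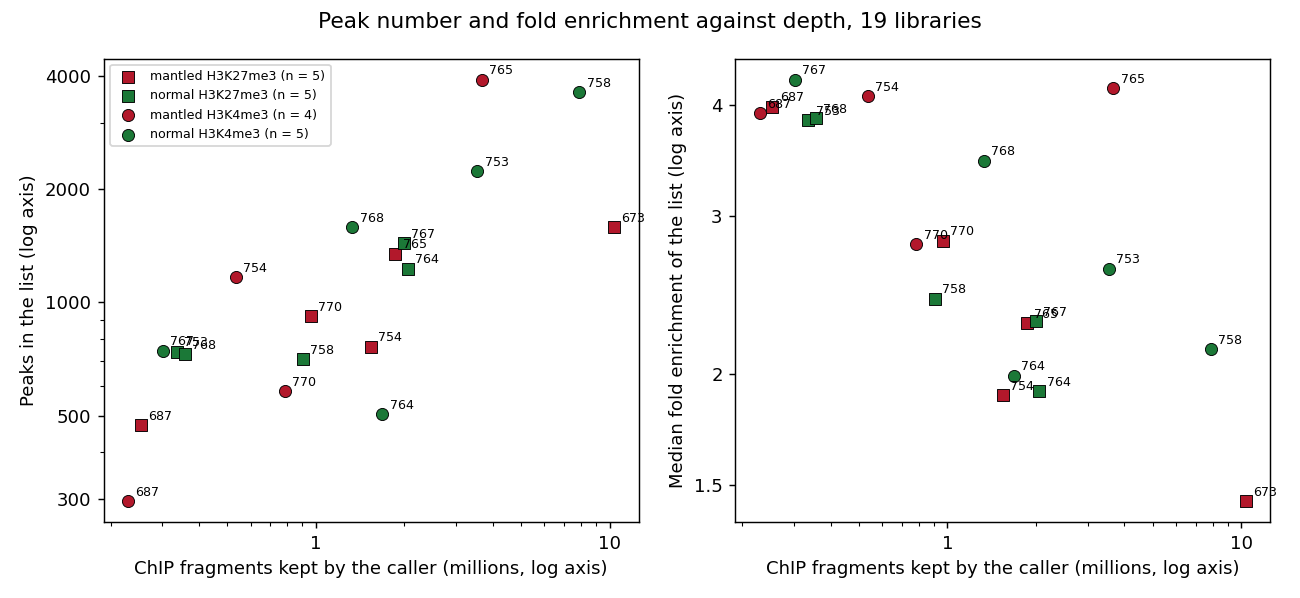
Peaks per list (left) and median fold enrichment per list (right) against ChIP fragments, all on log axes, 1 point per library labelled with its palm, circles for H3K4me3 and squares for H3K27me3, green for normal and red for mantled palms. Mantled palm 673 has the deepest H3K27me3 library, at 10374962 fragments, and the lowest median fold enrichment, at 1.44.

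The similarity of peak lists within and between phenotypes did not differ beyond the spread over label assignments. For H3K4me3 the mean Jaccard index was 0.198 within and 0.157 between phenotypes, a difference of 0.0409 (exact permutation p = 0.159, n = 4 and 5). For H3K27me3 it was 0.201 within and 0.230 between, a difference of -0.0298 (exact permutation p = 0.278, n = 5 and 5). Single pairs of H3K4me3 lists ranged from 0.0181 to 0.495. The H3K4me3 difference was 0.0841 when equal numbers of the strongest peaks were compared (exact permutation p = 0.0317, n = 4 and 5) and 0.1 without mantled palm 765 (exact permutation p = 0.0357). It was -0.0022 without normal palm 753, -0.00318 without normal palm 768, and 0.0115 with the marks of palm 754 exchanged (exact permutation p = 0.971, 0.943 and 0.778).

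The next comparison set the marks against each other. Peak number did not differ beyond the spread between libraries, with 1.25 times as many H3K4me3 as H3K27me3 peaks (exact permutation p = 0.486, n = 9 and 10), and 5 of 9 palms had more H3K4me3 peaks. The median H3K4me3 peak was 0.764 times as wide as the median H3K27me3 peak (exact permutation p = 0.0153, n = 9 and 10), and it was the wider of the pair in 1 of 9 palms. Median widths ranged from 298 to 477 bp for H3K4me3 lists and from 324 to 770 bp for H3K27me3 lists. The marks were called in different modes, narrow and broad, and the width ratio was 1.00 among peaks with a fold enrichment of at least 3 (exact permutation p = 0.994, palm 673 left out, n = 9 and 9). With the marks of palm 754 exchanged it was 0.809 (exact permutation p = 0.0698, n = 9 and 10).

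Many regions carried peaks of both marks. Of the 5888 regions merged over both marks, 2759 had peaks of both, 2432 of H3K4me3 only and 697 of H3K27me3 only. Of the 1385 regions with H3K27me3 in at least 3 libraries, 1102 (79.6%) also had H3K4me3 in at least 3, and 12 had no H3K4me3 peak in any library. Of the 1977 regions with H3K4me3 in at least 3 libraries, 55.7% had H3K27me3 in at least 3, and 268 had no H3K27me3 peak in any library. These counts take the mark labels as given, and the first share was 68.7% and the second 52.6% with the marks of palm 754 exchanged, 71.9% and 51.4% without palm 754, and 68.0% and 20.1% without the 5 H3K27me3 libraries that covered more of the H3K4me3 set defined below (673, 754, 765, 767 and 768), where the same 3 libraries had to come from 5 instead of 10. A peak was present in all 19 libraries at 46 regions on 41 pieces. The highest-ranked was p5.00_sc00001_p0869 from 6536 to 7062, with median fold enrichments of 3.88 ± 2.13 for H3K4me3 (SD, n = 9) and 3.58 ± 1.2 for H3K27me3 (SD, n = 10). It was followed by p5.00_sc00252_p0006 from 952 to 2038 at 3.52 ± 1.15 and 2.96 ± 1.23, p5.00_sc00087_p0065 from 15432 to 16887 at 3.47 ± 0.741 and 2.91 ± 0.609, p5.00_sc00006_p0088 from 7551 to 7820 at 3.10 ± 0.800 and 2.64 ± 0.700, and p5.00_sc02514_p0001 from 15715 to 17853 at 2.76 ± 1.33 and 2.12 ± 0.574, in the same order of marks. The local background at the 46 regions was 18.3 to 583 times the average at the caller's genome size. High background was not confined to them. It was over 10 times that average at 29.5 to 86.5% of the peaks of an H3K4me3 list (mean 54.9%, n = 9). In H3K27me3 lists the share was 44.1 to 79.0% (mean 62.2%, n = 10). These shares are over all peaks of a list, not over the regions with both marks.

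The overlap of lists of the same mark did not exceed that of lists of different marks beyond the spread over assignments of the marks. Between palms, the mean overlap was 58.7% of the shorter list within a mark and 56.8% between marks, a difference of 1.89 percentage points (one-sided exact permutation of the marks within palms, p = 0.191, 9 palms). The marks went opposite ways: over all palms the mean was 63.9% for pairs of H3K4me3 lists and 52.4% for pairs of H3K27me3 lists, against 57.3% for pairs of different marks. Without palm 754 the difference was 7.86 percentage points, the highest of the 9 values with 1 palm left out. That palm was picked after its lists had been seen, so no p is given. Without palm 753 the difference was -0.0187 (one-sided exact permutation p = 0.438, 8 palms). The H3K4me3 and H3K27me3 lists of the same palm overlapped by 61.1% ± 17.9 (SD, n = 9) and those of different palms by 56.8% (one-sided exact permutation of the pairing, p = 0.227, 9 palms).

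**Figure D2:**
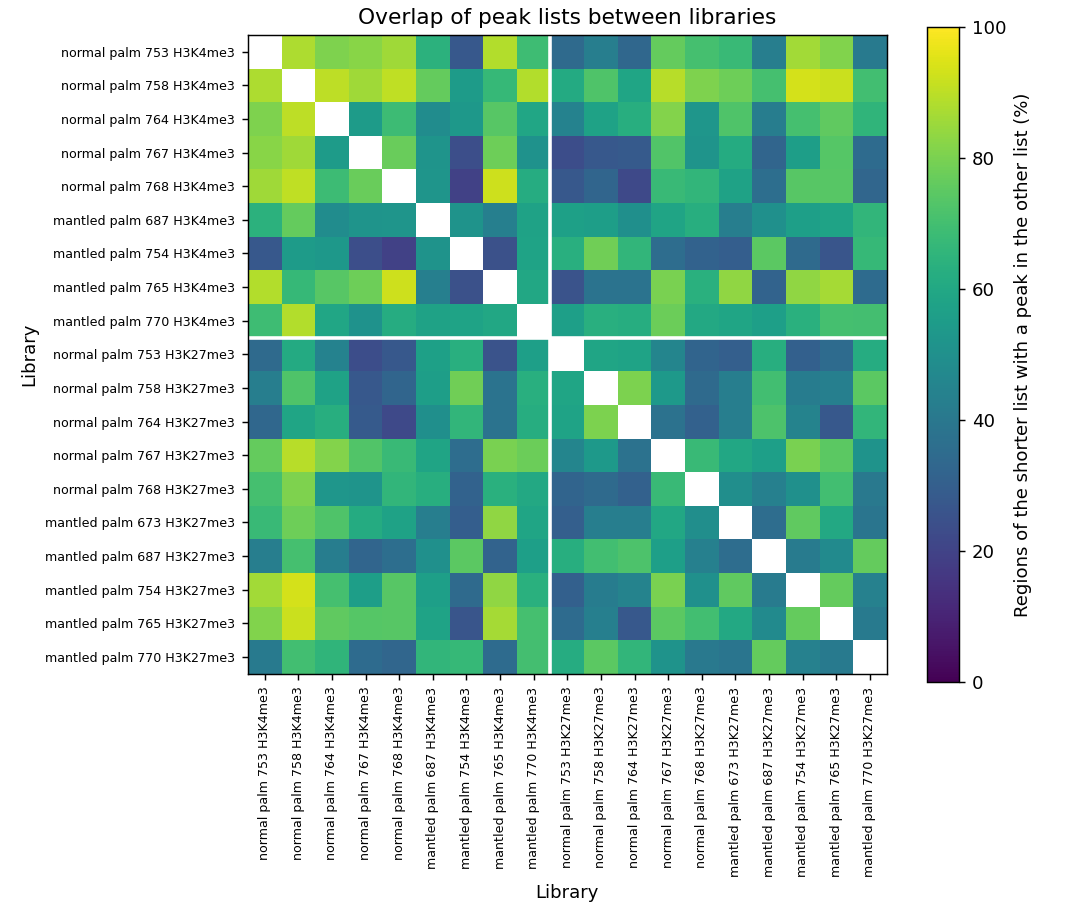
Overlap of each pair of the 19 peak lists, as the percentage of the shorter list's regions with a peak in the other list (colour scale from 0 to 100%), with white lines between H3K4me3 and H3K27me3 libraries. The library labelled H3K4me3 of mantled palm 754 overlaps H3K27me3 of normal palm 758 by 78.4% and H3K4me3 of normal palm 768 by 19.4%.

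Regions specific to a mark in the normal palms were then looked up in each library. Of the 678 regions of the H3K4me3 set, mantled palm 765 had an H3K4me3 peak at 96.8% (95% Wilson interval 95.1 to 97.8%). The H3K4me3 libraries of mantled palms 687 and 770 covered 1.62% (0.908 to 2.88%) and 3.69% (2.51 to 5.39%) of it, and 6.34% (3.74 to 10.5%) and 38.5% (32.1 to 45.4%) of the 205 regions of the H3K27me3 set. The library labelled H3K4me3 of mantled palm 754 covered 2.06% of this set (1.23 to 3.44%) and 91.7% of the H3K27me3 set (87.1 to 94.8%). The H3K27me3 library of palm 770 covered 86.3% of the H3K27me3 set (81.0 to 90.4%) and 4.28% of the H3K4me3 set (2.99 to 6.08%), and that of palm 687 covered 46.3% (39.6 to 53.2%) and 1.18% (0.599 to 2.31%). The reverse order held in 3 mantled libraries labelled H3K27me3. Palm 765 covered 64.9% of the H3K4me3 set (61.2 to 68.4%) and 13.2% of the H3K27me3 set (9.21 to 18.5%), palm 673 covered 55.8% (52.0 to 59.4%) and 26.3% (20.8 to 32.8%), and palm 754 covered 23.9% (20.8 to 27.2%) and 12.2% (8.40 to 17.4%). Each normal library was scored on its own sets, of 183 to 947 regions for H3K4me3 and 84 to 271 for H3K27me3. Their shares are therefore not comparable with one another. The H3K4me3 libraries of normal palms 753, 767 and 768 followed their labels by this measure. They covered 97.3, 24.8 and 79.6% of the H3K4me3 set and 14.0, 1.91 and 4.23% of the H3K27me3 set. So did the H3K27me3 libraries of normal palms 753, 758 and 764. These covered 1.89, 3.02 and 10.5% of the H3K4me3 set and 70.2, 86.4 and 90.5% of the H3K27me3 set. The H3K27me3 libraries of normal palms 767 and 768 covered more of the H3K4me3 set, 69.4% and 28.0%, than of the H3K27me3 set, 40.2% and 12.6%. Leaving them out enlarged the H3K4me3 set to 947 and 904 regions, and every added region had a peak in the library scored. The H3K4me3 library of normal palm 764 covered 7.39% of the H3K4me3 and 17.6% of the H3K27me3 set, which had grown to 245 regions in the same way. On these sets the order in these 3 libraries therefore cannot be told from the leave-out rule. Their order on the full sets of 678 and 205 regions was not computed. The H3K4me3 library of normal palm 758, also in the order of its label, covered 98.9% of the H3K4me3 and 71.6% of the H3K27me3 set. The common set of 290 regions was covered to between 47.2 and 88.6% in the mantled libraries.

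**Figure D3:**
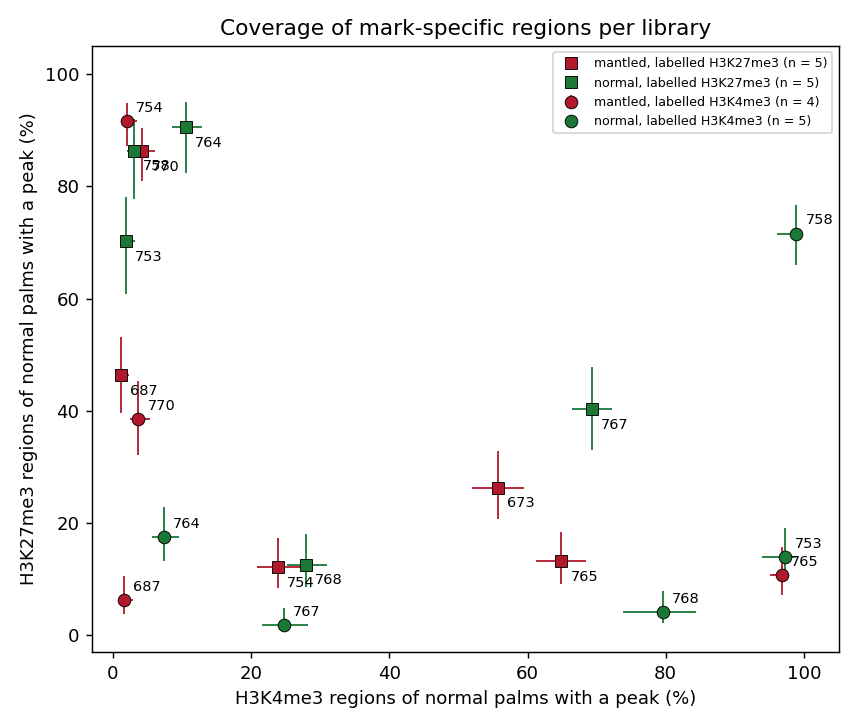
Share of the H3K4me3 set (horizontal, %) and of the H3K27me3 set (vertical, %) of normal palms with a peak in each library, with 95% Wilson intervals as bars and palm numbers beside the points; circles are libraries labelled H3K4me3 and squares H3K27me3, green normal and red mantled. The circle of mantled palm 754 lies among the H3K27me3 squares at 2.06% and 91.7%. Each normal library is scored on sets made without it, which biases its order against its label.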

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

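All tests in this part except the counts over splits were chosen after the values had been seen. A library was singled out where its distance to the nearest other library of its group was large against the range of the group. This was examined for 36 groups of 4 or 5 libraries, and chance alone singles out about 1 in 20 groups. The H3K27me3 library of mantled palm 673 held 10374962 fragments, against 1865140 in the next deepest of its group. The H3K4me3 library of mantled palm 765 held 3670206 fragments against 783650 in the next, its peaks covered 2501 kb against 491 kb, and it covered 96.8% of the H3K4me3 set against 3.69%. The H3K4me3 library of normal palm 758 covered 71.6% of the H3K27me3 set against 17.6% in the next. Each was scored on sets made without it, so both shares are raised by construction. In the H3K4me3 library of normal palm 764, 86.5% of the peaks lay where the local background was over 10 times the average at the caller's genome size, against 50.6% in the next.

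Over all 9 palms the overlap of lists within a mark exceeded that between marks by 1.89 percentage points, which did not pass its test. The excess was 7.86 points without palm 754. With the marks of palm 754 exchanged it was 10.3 points, an exchange picked as the highest of the 256 assignments. How small the excess was over all 9 palms was weighed against 3 technical explanations. An exchange of the mark labels in palm 754 is a candidate explanation for part of this. Its library labelled H3K4me3 had a peak at 91.7% of the H3K27me3 set and 2.06% of the H3K4me3 set. Its library labelled H3K27me3 had a peak at 23.9% of the H3K4me3 and 12.2% of the H3K27me3 set. On that side palm 754 is the lowest of the mantled libraries in reversed order, which covered up to 64.9% of the H3K4me3 set (765). The direction alone is not particular to palm 754. Mantled palms 687 and 770 shared it in H3K4me3 libraries, and mantled palms 765 and 673 in H3K27me3 libraries. Of the 9 palms, 4 libraries labelled H3K4me3 (687, 754, 764 and 770) and 4 labelled H3K27me3 (754, 765, 767 and 768) were reversed. In 1 palm, 754, both were, where independence of the libraries gives 1.78. These counts include normal palms 764, 767 and 768, whose order is biased against the label by the leave-out rule. They decide nothing about palm 754. An exchange in palms 765, 767 and 768 is argued against, since their libraries labelled H3K4me3 covered at most 10.7% of the H3K27me3 set and more of the H3K4me3 set. Sequencing depth as the whole cause could not be settled. In 9 of the 16 pairs of mantled libraries of 1 mark, one covered more of the H3K4me3 set and less of the H3K27me3 set. The 95% intervals were apart on both. This argues against depth only if depth raises or lowers both shares, which was not tested. Coverage of the H3K4me3 set went with depth in the mantled libraries. In H3K4me3 libraries it rose from 1.62% at 229258 fragments (687) to 96.8% at 3670206 (765). In H3K27me3 libraries it rose from 1.18% at 253624 fragments (687) to 64.9% at 1865140 (765), and was 55.8% at 10374962 (673). In the normal libraries, each scored on sets of its own and so not strictly comparable, coverage did not rise steadily with depth. For H3K4me3 it was 24.8% at 302016 (767), 79.6% at 1331454 (768), 7.39% at 1683525 (764), 97.3% at 3544422 (753) and 98.9% at 7883375 (758). For H3K27me3 it was 1.89% at 336380 (753), 28.0% at 356982 (768), 3.02% at 903822 (758), 69.4% at 1998875 (767) and 10.5% at 2056297 (764). Depth, cross-reacting antibody, a single wrong label and differences between the palms stay open, and the last 3 were not tested.

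The split by phenotype gave 0 separated regions in each mark. A count of 0 is matched by all splits (126 of 126) whatever the data, so the count over splits decides nothing about chance here. For H3K4me3 the highest other split gave 531 regions. It set palms 753, 758, 765 and 768, whose lists were the longest at 1584 to 3910 peaks, against lists of 296 to 1168 peaks, and all 531 regions lay in the long lists. For H3K27me3 the highest other split gave 123. Each is the highest of all splits, and what lists of these lengths would give without any grouping was not computed.

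The 46 regions with a peak in all 19 libraries were weighed against multicopy sequence collapsed in the assembly. The median local background there was 216 times the average at the caller's genome size, as a median over the 19 libraries, against 11.2 times at the other peaks, and it was higher in 19 of 19 libraries; a larger genome size would raise both multiples alike. The median fold enrichment there was 1.96 against 2.91, and lower in 19 of 19 libraries. Fold enrichment is a ratio to this background, so its lower values are not separate evidence. The background values are such as multicopy sequence could give, of which plastid-derived sequence could be one kind. The sequence of the regions was not analysed here. Presence of both marks at these regions was not tested separately and stays open.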

How the results depend on the processing

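The exchange of marks in palm 754, leaving out palm 754 or 673, and the alternatives for the overlap of lists of both marks were chosen after seeing the data. Over 93 alternative settings of the 6 phenotype tests, 3 gave an exact permutation p under 0.05, each for H3K4me3. At a fold enrichment of at least 3 the difference in log2 H3K4me3 peak number turned to 0.43 and that in median enrichment was 0.32 (exact permutation p = 0.0317); with equal numbers of strongest peaks the similarity difference was 0.0841 (p = 0.0317), and without palm 765 it was 0.1 (p = 0.0357). With peak numbers divided by fragments the log2 difference in peak number turned to 0.68 for H3K4me3 and to -0.79 for H3K27me3, and at a fold enrichment of at least 3 without palm 673 it turned to -0.59 for H3K27me3. Separated H3K4me3 regions numbered 1 at a −log10 q of at least 5 (on p5.00_sc01104_p0001, mantled) and 1 with equal numbers of strongest peaks (on p5.00_sc01787_p0001, normal); 52 and 45 of 126 splits gave as many. A difference of at least 0.6 in the share of libraries was met by 58 H3K4me3 and 69 H3K27me3 regions, with up to 1442 and 810 in other splits. Leaving out each library gave 0 to 40 separated H3K4me3 and 0 to 1 separated H3K27me3 regions, log2 differences in peak number from -1.23 to 0.016 and from -0.18 to 0.26, in median enrichment from 0.29 to 0.57 and from -0.43 to -0.062, and similarity differences from -0.00318 to 0.1 and from -0.0403 to -0.0067, for H3K4me3 and H3K27me3. With the palm as a replicate block, the log2 difference between marks was 0.41 in peak number (exact sign-flip p = 0.383) and -0.30 in median width (exact sign-flip p = 0.0352), so the block changed no call. The width difference was 0.00073 at a fold enrichment of at least 3 without palm 673 and -0.31 with the marks of palm 754 exchanged (exact permutation p = 0.0698), where the call was lost; without single libraries it ranged from -0.45 to -0.30, and that in peak number from 0.10 to 0.57. The overlap difference between marks was 10.3 percentage points with the marks of palm 754 exchanged (an exchange picked as the highest of the 256 assignments, so no p is given) and ranged from -0.0187 to 7.86 without single palms; it was 0.908 with equal numbers of strongest peaks (exact permutation p = 0.230), 2.47 at a −log10 q of at least 5 (p = 0.164), 2.80 by base-pair Jaccard (p = 0.082) and 4.27 at a fold enrichment of at least 3 without palm 673 (p = 0.0781). Of the 40 named regions, 11 had a number of libraries changed by over 1.5 times at a −log10 q of at least 5, and 22 at a fold enrichment of at least 3. Except where the setting shows it, the cause was not tested. The list of palm 673 has no peak of that enrichment, so the H3K27me3 and mark comparisons at that threshold were run only without it. Settings restricted to chromosomes and all settings of gene windows were not run for lack of chromosome names and a matching annotation, and equal list lengths leave no peak number to compare. Depth limits the lists: 6 of the 19 libraries held under 600000 fragments, and peaks missing from them may lie below detection.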

Other observations

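Within 4 of the 13 libraries with at least 20 peaks in each of the mark-specific sets, the peaks at the H3K27me3 set were the wider. In 9 of the 13 the peaks at the H3K4me3 set had the higher median fold enrichment. In the H3K4me3 library of mantled palm 765 the medians were 700 bp and 7.36-fold at the H3K4me3 set against 286 bp and 1.80-fold at the H3K27me3 set. In the H3K27me3 library of mantled palm 770 they were 305 bp and 2.73-fold against 430.5 bp and 2.98-fold. In the H3K27me3 library of normal palm 764 they were 861 bp and 1.56-fold against 644 bp and 2.65-fold.

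The piece p5.00_sc02514_p0001 held 3 of the 46 regions with a peak in all 19 libraries. The input paired with H3K27me3 was the deeper of a palm's 2 inputs in 7 of 9 palms, and the exceptions were palms 754 and 758, with ratios of 0.79 and 0.936. The overlap of the H3K4me3 and H3K27me3 lists of a palm ranged from 34.5% of the shorter list in palms 753 and 754 to 86.7% in palm 765.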
